A study of Mus musculus with 24 samples.

How the data were processed

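Hearts of male mice homozygous for the Clock Δ19 mutation were collected at 8 weeks of age under a cycle of 12 h of light and 12 h of darkness, at 6 time points 4 h apart, with 4 biological replicates per time point and 24 arrays in all. Per the labels' protocols, hearts were snap frozen, total RNA was extracted with TRIzol, and biotin-labelled cRNA was made from 500 ng of total RNA by the Affymetrix protocol for arrays of a single colour. Wild-type hearts were not analysed here, so no comparison between genotypes was made.

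The deposited values are on a log scale, taken here as log2, and the authors had centred each of the 34351 features on its own median over the 24 arrays (largest absolute median of a feature 5e-07). The values run from -1.89 to 2.11, and the median of an array lies between -0.0080 and 0.0023. The summarization of probes, the normalization between arrays, the log base and any filter before deposit were not given in the sources used here. The spacing of the deposited numbers is that of single-precision numbers from which a median was subtracted: 666 features (1.94%) lie on the grid of numbers between 8 and 16 before centring and the other 33685 on that of numbers between 4 and 8, each within 1e-07. This leaves out a log10 of scanner brightness but not a natural log. Adjusted p-values do not depend on the base, while every size called log2 below would be 1.44 times larger if the base were e. Because each feature is centred, the values hold no level beyond these 2 classes, levels of different genes cannot be set against each other, and signal over background is unknown. The number of arrays, 4 per time point, limits the precision; the median SD within time points was 0.087 over genes.

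Features were named through the platform annotation: 23521 features had 1 gene symbol, 1814 had several and 9016 had none, and features with several or none were not used for named genes. Of the features with 1 symbol, 23328 matched an Entrez gene in the RefSeq table of GRCm38.p6, and 0 of those symbols differed; no coordinates were used. Features of a gene were averaged, which concerned 2423 features of 1082 genes, and left 22180 genes. The design fixed before the data were examined, in which the tests, named-gene rule, gene lists and most alternatives were chosen, asked for the feature with the highest mean and for leaving out genes of low mean level. Centred values have no mean level, and the 2 classes of the number grid do not rank features within a class, so neither rule could be applied: all 22180 genes were tested, without a filter.

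All tests used limma 3.58.1 in R 4.3.3, with moderated F or contrast tests and Benjamini-Hochberg adjustment at 0.05. A fit of 6 time-point means gave the F test of any difference among time points, the contrast of the light phase (ZT03, ZT07, ZT11) minus the dark phase (ZT15, ZT19, ZT23) and 3 contrasts of time points 12 h apart. Zeitgeber time (ZT) counts hours from lights on. A cosine and sine pair of period 24 h was tested as a 24 h rhythm, with the amplitude defined as the distance from mean to peak, and a pair of period 12 h was tested beside it. With 1 cycle sampled, a 24 h term describes the profile and does not show that it repeats. Errors are SE of the fit unless an SD is named, and n is 4 hearts per time point. Linear algebra of the fits was checked against lmFit and eBayes, with log10 p differing by at most 8e-15.

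The named genes followed a fixed rule: all measured core clock genes, up to 6 genes of the largest amplitude in each of 4 windows of peak time, the 10 largest light-dark differences in each direction, the 5 largest in each direction for each pair of opposite time points, up to 10 genes of the 12 h test, up to 4 members of each list with the smallest p of the 24 h test, and the 10 smallest p-values of the time-of-day test. Where 0 genes passed, the 5 with the smallest p were named as not passing. Other list members named below are those that passed a test over all genes or adjusted over the list alone. Gene models without a proper symbol were counted, not named. Counts of hearts to one side are given for genes chosen on the same hearts. They describe these genes and are no separate support. The 35 gene lists, 21 of pathways and 14 of cell types, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with fry, with Fisher's exact test, and, for the mean of a list over 24 h, by a permutation test with 100000 permutations of the time labels.

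On simulated data with 200 of 22180 genes changed, the 24 h test recovered 58% of genes at an amplitude of 0.1 and 88% at 0.2, and the time-of-day test 34% and 80%. For ZT03 against ZT15, 50% of genes changed by 0.2 and 80% of genes changed by 0.4 were recovered. For ZT07 against ZT19 the shares at these sizes were 36% and 82%, for ZT11 against ZT23 38% and 78%. The 12 h test recovered 30% at an amplitude of 0.1, and the light-dark contrast 88% at a difference of 0.2. The simulated noise was independent between genes. In the simulation the 24 h test called 184 genes, where the data gave 14, so its threshold on unadjusted p was less strict. The same was true of the 12 h test (160 against 1) and light against dark (203 against 84). It was also true of ZT07 against ZT19 (166 against 0) and ZT11 against ZT23 (165 against 0). The shares of these tests may therefore be too high for the data. They do not show that the pairs with 0 calls had the power of ZT03 against ZT15 (173 against 239).

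The alternatives fixed beforehand were another normalization between arrays (quantile, or centring each array), no moderation across genes, array weights, the replicate number as a block, atrial or blood markers as a covariate, a stricter threshold, smaller fits, and each heart left out in turn. Chosen after seeing the data were robust moderation without an intensity trend, every feature tested on its own, only genes with a feature above 8 before centring, small nuclear and nucleolar RNA as a covariate, leaving out both arrays of lowest weight, leave-outs for the gene lists, the means of other cell type lists as a covariate for ZT03 against ZT15, and core clock amplitudes without 1 ZT19 heart. Tool versions of the labelling and scanning steps were not given in the sources used here.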

Results

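Transcript levels were measured on arrays in the hearts of 24 male mice homozygous for Clock Δ19. The mutation removes an exon from the Clock transcript and leaves a protein that does not activate transcription, which impairs the feedback loop of the circadian clock. Hearts were taken at ZT03, ZT07 and ZT11 in the light phase and at ZT15, ZT19 and ZT23 in the dark phase, 4 hearts per time point. The question addressed is which cardiac transcripts still differ over a light-dark cycle in these mice. All values are differences on a log scale, taken as log2, around each gene's own median over the 24 arrays, and the number of arrays limits their precision. The mean of Clock was -0.23 ± 0.05 (SD, n = 4) at ZT11, -0.16 ± 0.29 (SD) at ZT19 and 0.09 ± 0.06 (SD) at ZT23. The ZT19 value rests on replicate 2, at -0.60, while the other hearts were at 0.014, -0.011 and -0.060. Where the probes of the Clock feature lie was not given in the sources used here, so its value checks nothing about the deleted exon.

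Among the genes that differed between time points, Cryab, which codes for the small heat shock protein αB-crystallin, had the smallest p-value. Cryab lay at -0.38 ± 0.05 (SD, n = 4) at ZT03 and -0.29 ± 0.05 (SD) at ZT07, against 0.15 ± 0.13 (SD) at ZT11 (adjusted p with limma 0.00039). Lpl, which codes for lipoprotein lipase, went from -0.30 ± 0.05 (SD) at ZT03 to 0.22 ± 0.12 (SD) at ZT11 (adjusted p = 0.0025). Prdx3, which codes for a mitochondrial peroxidase, ran the other way, from 0.38 ± 0.04 (SD) at ZT03 to -0.13 ± 0.06 (SD) at ZT11. Tmem65 fell from 0.29 ± 0.08 (SD) at ZT03 to -0.16 ± 0.05 (SD) at ZT23. Mr1, which codes for a protein that presents vitamin metabolites to T cells, lay at 0.54 ± 0.15 (SD) at ZT03 and -0.32 ± 0.24 (SD) at ZT11. For Cryab, Lpl, Prdx3, Tmem65 and Mr1, all 4 ZT03 hearts lay to one side of all 4 ZT15 hearts. The values of Cryab and Lpl average 2 features each, which differed in size: ZT03 minus ZT15 was -0.23 and -0.69 for those of Cryab and -0.13 and -0.70 for those of Lpl. Arhgap20, Pcdh7, Mospd1 and Apool were highest at ZT03 or ZT07, and Tmem63b was lowest at ZT03.

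In all, 329 of 22180 genes passed the F test over the 6 time points with limma, and 2973 had an unadjusted p under 0.05 where chance gives 1109. Of the 329 genes, 197 had their highest mean at ZT03, 46 at ZT07, 29 at ZT11, 16 at ZT15, 23 at ZT19 and 18 at ZT23. The lowest mean fell at ZT11 for 128 genes, at ZT23 for 77 and at ZT15 for 62. The genes named above passed with every heart left out in turn, but the counts moved. Without ZT03 replicate 1 the count was 180, of which 109 were highest at ZT03 and 60 lowest at ZT11. These 3 numbers were 145, 77 and 51 without ZT03 replicate 2, and 28, 17 and 5 without ZT03 replicate 3. They were 182, 122 and 70 without ZT07 replicate 3, and 189, 114 and 64 without ZT11 replicate 3. The count was 211 without ZT11 replicate 2, with 84 genes lowest at ZT11. Genes lowest at ZT11 numbered 63 without ZT11 replicate 1 and 250 without ZT11 replicate 4.

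Over a 24 h cosine, Srsf5, which codes for a splicing factor, had a fitted amplitude of 0.27 ± 0.04 with a peak at ZT5.31 (adjusted p with limma 0.0048). For Srsf5, 20 of 24 hearts lay on the side of the mean that the curve gave. Prrx1, a homeobox gene of mesenchymal cells, had an amplitude of 0.18 ± 0.02 with a peak at ZT1.90 (adjusted p = 0.0048, 22 of 24 hearts). Tppp, whose protein promotes tubulin polymerization, had an amplitude of 0.17 ± 0.02 with a peak at ZT17.1 (adjusted p = 0.0048, 19 of 24 hearts). Bst2, the interferon-induced gene of tetherin, had an amplitude of 0.34 ± 0.06 with a peak at ZT17.8 (adjusted p = 0.033, 20 of 24 hearts). Cryab had an amplitude of 0.23 ± 0.04 with a peak at ZT15.6. Peaks between ZT0 and ZT6 were also fitted for the prostaglandin transporter gene Slco2a1 (amplitude 0.20), the SUMO protease gene Senp6 (0.17), Slf2 (0.13) and the hypoxia factor gene Hif1a (0.10, with 0.15 and 0.04 for its features). Magi3 (0.22) and Cdh2, which codes for N-cadherin (0.12), peaked between ZT6 and ZT12. Ccar1 (0.18) peaked close to ZT18 and Gtf2f1 (0.15) at ZT21.1.

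**Figure D1:**
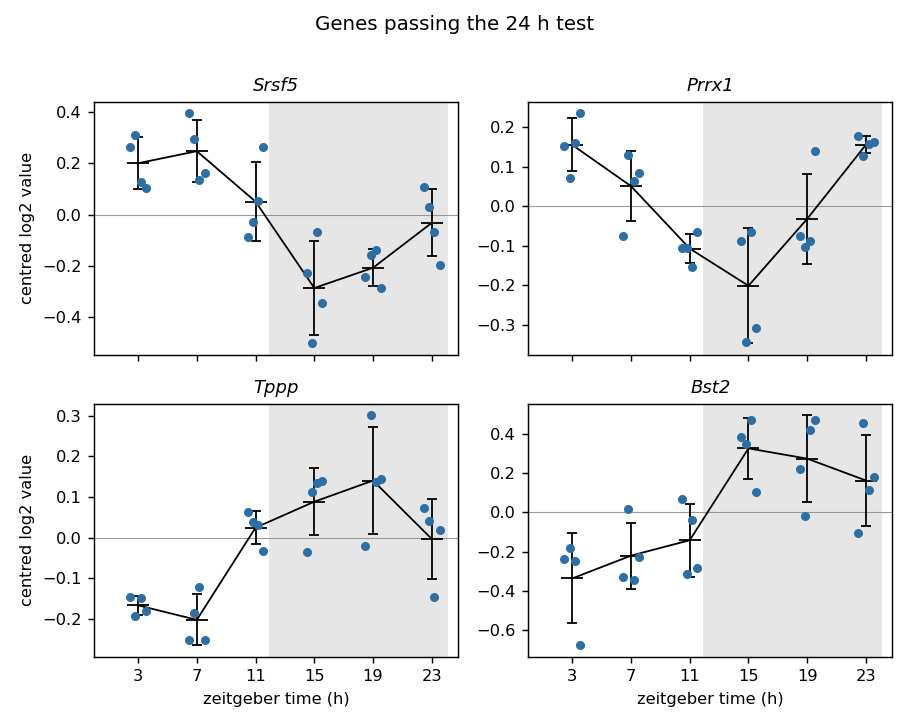
Centred log2 values (vertical axes) against zeitgeber time in hours (horizontal axes) for 4 genes that passed the 24 h test; each point is 1 heart, the bars are the mean ± SD of 4 hearts, and the grey area is the dark phase. Fitted peaks were at ZT5.31 for Srsf5, ZT1.90 for Prrx1, ZT17.1 for Tppp and ZT17.8 for Bst2.

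In all, 14 genes passed the 24 h test with limma, 1 of them without a proper symbol, and 2403 had an unadjusted p under 0.05. Their fitted peaks fell 6 times between ZT0 and ZT6, 3 times between ZT6 and ZT12, 4 times between ZT12 and ZT18 and 1 time later. All 14 genes were among the 329 genes of the time-of-day test. A fitted peak-to-trough fold of 1.5 was reached by 2 genes, Bst2 and the gene without a proper symbol, and would be reached by 5 if the values were natural logs. Prrx1, Srsf5 and Tppp passed with each heart left out, while each of the other 10 named genes missed the threshold without at least 1 heart. The count was 3 without ZT03 replicate 1, ZT03 replicate 3 or ZT11 replicate 2, 5 without ZT15 replicate 4, and 6 without ZT07 replicate 3 or ZT07 replicate 4. It was 7 without ZT07 replicate 1, ZT07 replicate 2 or ZT19 replicate 3, 8 without ZT15 replicate 1 and 9 without ZT23 replicate 2. It was 29 without ZT23 replicate 1 and 45 without ZT19 replicate 4.

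Arntl, which codes for the partner of CLOCK, had a 24 h amplitude of 0.26 ± 0.07 with a peak at ZT1.37, and its mean went from 0.24 ± 0.19 (SD, n = 4) at ZT03 to -0.34 ± 0.09 (SD) at ZT11. Per1, a repressor gene of the clock, had an amplitude of 0.31 ± 0.08 with a peak at ZT9.65, and Nfil3, which codes for a repressor of clock output genes, 0.19 ± 0.04 with a peak at ZT20.5. The adjusted p with limma was 0.20 over all genes and 0.023 over the list for Arntl, 0.22 and 0.023 for Per1, and 0.11 and 0.0098 for Nfil3. Npas2, a paralog of Clock, had an amplitude of 0.16 (peak ZT4.37), Cry1 0.16 (peak ZT20.6) and Rorb 0.10 (peak ZT4.27). Clock itself had an amplitude of 0.12 ± 0.04 with a peak at ZT2.05 (adjusted p = 0.40 over all genes, 0.085 over the list). The other amplitudes were 0.15 for Nr1d1, 0.11 for Nr1d2, 0.11 for Per3, 0.08 for Dbp, 0.08 for Cry2, 0.04 for Hlf, 0.04 for Bhlhe41, 0.03 for Tef and 0.02 for Ciart. They were 0.09 for Arntl2, 0.08 for Bhlhe40, 0.05 for Timeless, 0.01 for Csnk1e and 0.01 for Rora. Of the 21 measured core clock genes, 0 passed the 24 h test over all genes with limma, 9 had an unadjusted p under 0.05, and 6 passed adjusted over the list alone: Arntl, Per1, Nfil3, Npas2, Cry1 and Rorb. With 12 h terms fitted beside, Nfil3 passed over all genes. In the F test over time points, Nfil3 passed over all genes (adjusted p = 0.018), and 5 genes passed adjusted over the list alone. In the light phase, Nfil3 was lower over all genes (-0.24), and adjusted over the list alone 3 genes were higher (Per1, Npas2 and Arntl2) and 2 lower (Nfil3 and Cry1). The list held more genes with an unadjusted p under 0.05 in the 24 h test than other genes did (one-sided Fisher's exact test, adjusted p = 0.0021 over 35 lists), as did the lists of heat shock (5.5e-05), glucocorticoid response (0.0019), antioxidant (0.018) and oxidative phosphorylation genes (0.025). This test takes genes as independent. The permutation test of the list mean over 24 h does not, and it passed for none of these 5 lists. By it the adjusted p was 0.83 for core clock, 0.28 for glucocorticoid response and 0.11 for each of the other 3. Members with different peak times, such as Arntl (ZT1.37), Per1 (ZT9.65) and Nfil3 (ZT20.5), cancel in a list mean. The permutation test therefore cannot decide whether single members vary over 24 h. The count of core clock genes adjusted over the list alone was 3 without ZT11 replicate 1, ZT11 replicate 4 or ZT23 replicate 3. It was 1 without both arrays of lowest weight.

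**Figure D2:**
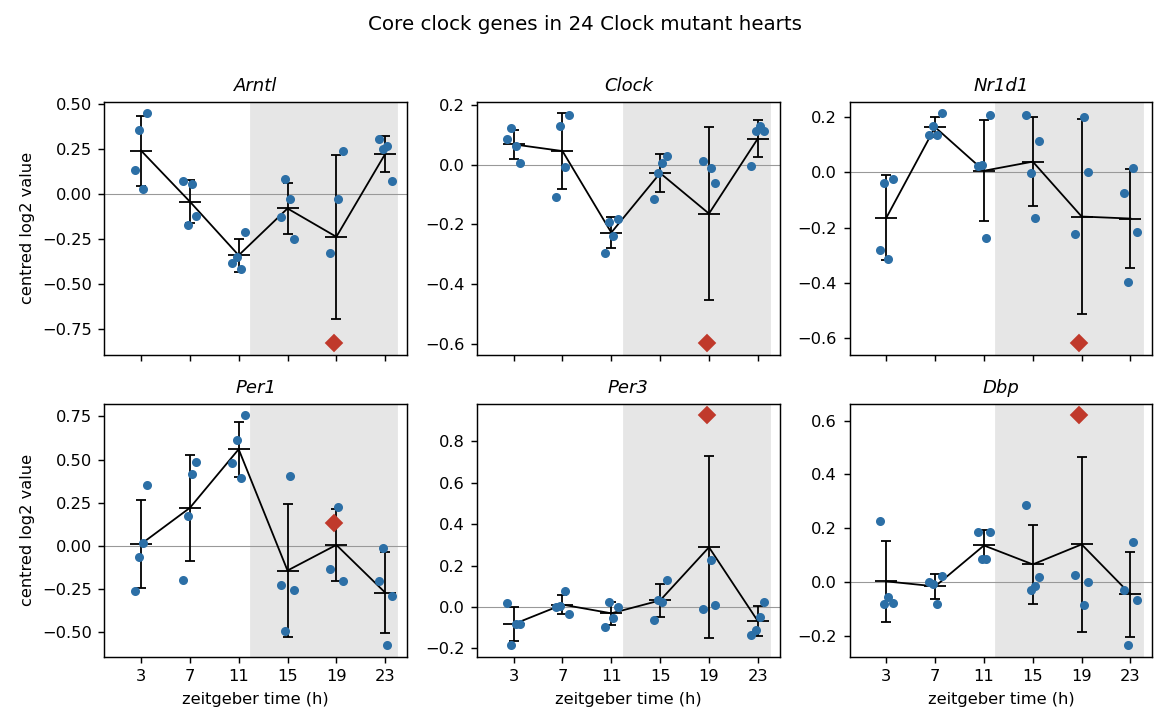
Centred log2 values (vertical axes) against zeitgeber time in hours (horizontal axes) for 6 core clock genes; each point is 1 heart, the bars are the mean ± SD of 4 hearts, the grey area is the dark phase and the red diamond is ZT19 replicate 2. The diamond is at -0.83 for Arntl, -0.60 for Clock and -0.62 for Nr1d1, below all other hearts, and at 0.93 for Per3 and 0.62 for Dbp, above them.

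ZT19 replicate 2 stood apart from the other hearts in these genes. Arntl was at -0.83 in it, with the lowest of the other hearts at -0.42, and Clock was at -0.60 against -0.30. Per3 was at 0.93 against a highest other value of 0.23, Nr1d2 at 0.67 against 0.23, and Dbp at 0.62 against 0.29. Nr1d1, in contrast to Nr1d2, was low, at -0.62 against a lowest other value of -0.40. In all, 12 of the 21 core clock genes lay outside the range of the other 23 hearts, against 0 to 4 in any other heart. Of all genes, 8.31% lay outside that range, where the other hearts had 6.16% to 16.2%. The 16.2% belonged to ZT11 replicate 1, which also had the lowest array weight (0.54) and the largest SD over features (0.153). Without ZT19 replicate 2, 0 core clock genes passed the 24 h test over all genes, and 5 passed adjusted over the list alone. These were Arntl (0.26, peak ZT0.294), Clock (0.12, peak ZT0.459), Npas2 (0.15, peak ZT4.13), Per1 (0.33, peak ZT9.43) and Nfil3 (0.21, peak ZT20.4). Cry1 and Rorb then missed the threshold over the list (adjusted p = 0.063 each). The amplitude of Per3 fell from 0.11 to 0.05, that of Nr1d1 went from 0.15 to 0.12 and that of Nr1d2 from 0.11 to 0.14.

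**Figure D3:**
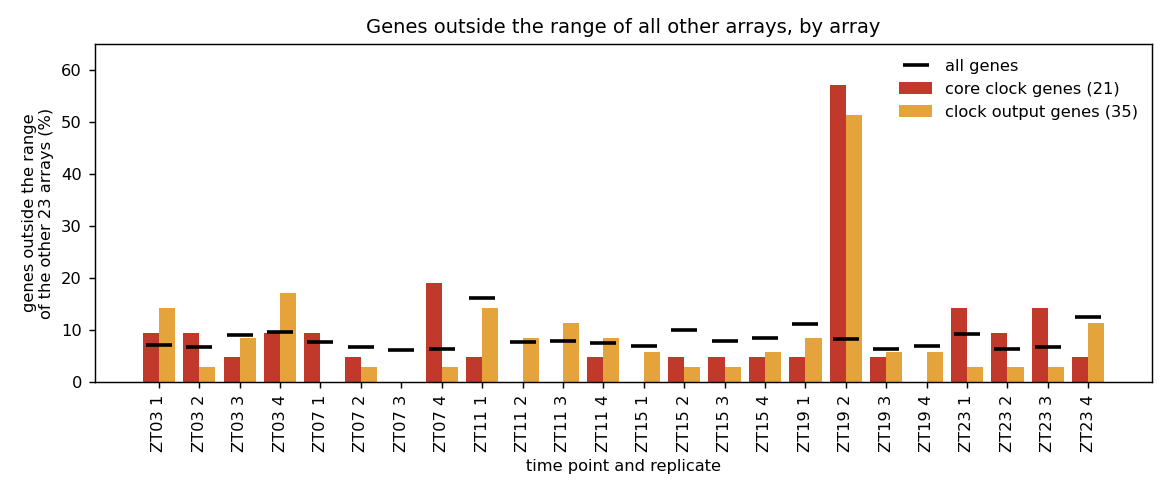
Percent of genes (vertical axis) whose value in 1 heart lay outside the range of the other 23 hearts, for each of the 24 hearts (horizontal axis), with bars for the 21 core clock genes and the 35 clock output genes and black dashes for all genes. For ZT19 replicate 2 the share was 57.1% of core clock genes and 8.31% of all genes.

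For the 12 h component, Pnpla8, which codes for a calcium-independent phospholipase, had an amplitude of 0.14. Its means were 0.13 ± 0.06 (SD, n = 4) at ZT03, -0.19 ± 0.13 (SD) at ZT11, 0.06 ± 0.06 (SD) at ZT19 and -0.13 ± 0.04 (SD) at ZT23, and all 4 ZT03 hearts lay above all 4 ZT15 hearts (adjusted p with limma 0.048). It was the 1 gene that passed, with 2335 at an unadjusted p under 0.05. The count was 0 when any one of 17 of the 24 hearts was left out. It was 51 without ZT03 replicate 4, 13 without ZT07 replicate 1, 14 without ZT07 replicate 2, 148 without ZT11 replicate 4, 43 without ZT15 replicate 3 and 14 without ZT19 replicate 2.

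In the light phase, Scin, which codes for an actin-severing protein, was higher by 0.48 ± 0.07 (adjusted p with limma 0.0085), and all 12 light-phase hearts lay above the median of the 12 dark-phase hearts. The neonatal Fc receptor gene Fcgrt was higher by 0.36 ± 0.07, the angiotensin II receptor gene Agtr1a by 0.32 ± 0.06, and Errfi1, which codes for a feedback inhibitor of the EGF receptor, by 0.32 ± 0.07, each in 12 of 12 hearts. Bst2 was lower in the light (-0.49 ± 0.08, adjusted p = 0.0091, 12 of 12 hearts), as were Abra, a gene of striated muscle (-0.43 ± 0.08, 12 of 12), and the immediate early gene Ier3 (-0.37 ± 0.07, 12 of 12). G0s2, which codes for an inhibitor of triglyceride lipase, was also lower (-0.32 ± 0.07, 11 of 12), as was the angiogenic factor gene Vegfa (-0.27 ± 0.05, 12 of 12). The collagen processing genes P4ha1 (-0.29) and Serpinh1 (-0.26) were lower too, with Rtn4r (-0.29) and Ccar1 (-0.24). Srsf5 (0.34), Scd4 (0.33), Nabp1 (0.32), Lrrc61 (0.31), Lclat1 (0.28) and Magi3 (0.28) were higher. The contrast passed for 84 genes, 54 higher and 30 lower in the light phase, and 2336 genes had an unadjusted p under 0.05. With limma, 0 of the 84 reached 1.5-fold, and 4 would if the values were natural logs. Of the 84 genes, 64 were among those of the time-of-day test and 11 among those of the 24 h test. The count was 51 without ZT03 replicate 3, 53 without ZT07 replicate 3 and 183 without ZT11 replicate 1. Of these 183 genes, 139 were higher and 44 lower in the light phase. With quantile normalization, 102 were higher and 42 lower. Of the genes named here, Scin, Srsf5, Agtr1a, Magi3, Bst2, Rtn4r, P4ha1, Vegfa and Ccar1 passed with each of the 24 hearts left out in turn, and Abra, Ier3 and Nabp1 with 23 of them. The others passed less often: G0s2 with 16 of the 24 left out, Errfi1 and Lrrc61 with 13, Lclat1 with 11, Fcgrt and Serpinh1 with 9 and Scd4 with 5.

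Some heat shock genes were lower in the light phase. Of the 20 measured members of this list, Cryab (-0.19), the constitutive chaperone gene Hspa8 (-0.32), Hspb1 (-0.17) and Fkbp4 (-0.18) were lower over all genes, in 9, 10, 11 and 12 of the 12 light-phase hearts. The features averaged here differed in size, at -0.08 and -0.31 for Cryab, -0.12 and -0.21 for Hspb1 and from -0.13 to -0.42 for the 4 of Hspa8. The mean of Cryab was nonetheless highest at ZT11, within the light phase (0.15). Adjusted over the list alone, 8 members were lower and 1 higher, the latter being Cirbp (0.12), whose protein is induced by cold. The median of the list was -0.11, which passed camera at the preset correlation (adjusted p = 3.1e-06). It did not hold with an estimated correlation (adjusted p = 0.15). The fry test, which asks whether the members move one way on balance and does not compare them with other genes, gave an adjusted p of 0.020. In the 24 h test, Cryab passed over all genes, and 6 members passed adjusted over the list alone, with fitted peaks from ZT13.5 for Bag3 to ZT22.6 for Chordc1.

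**Figure D4:**
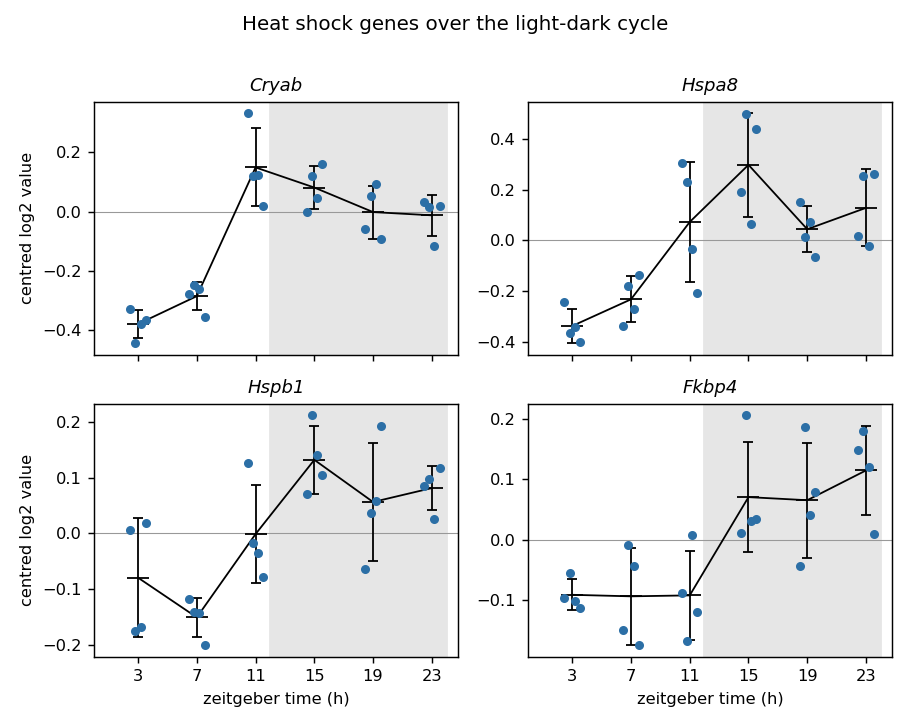
Centred log2 values (vertical axes) against zeitgeber time in hours (horizontal axes) for 4 heat shock genes; each point is 1 heart, the bars are the mean ± SD of 4 hearts, and the grey area is the dark phase. The lowest mean is at ZT03 or ZT07 for each gene, for example -0.38 for Cryab and -0.34 for Hspa8 at ZT03. For Fkbp4 the means at ZT03, ZT07 and ZT11 are nearly equal.

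With heat shock genes, 10 of 35 lists passed camera in the light-dark contrast at the preset correlation, of which 0 held with an estimated correlation (smallest adjusted p = 0.15). Lists lower at the preset correlation alone were those of endoplasmic reticulum stress (adjusted p = 0.23 with an estimated correlation), the interferon response (0.44), the sarcomere (0.49) and skeletal muscle (0.15). In the endoplasmic reticulum stress list (24 measured), 0 genes passed over all genes, and adjusted over the list alone 3 were lower, Herpud1 (-0.23), Pdia3 (-0.15) and Canx (-0.10), and 1 higher, Sel1l (0.13). In the interferon list (20 measured) Bst2 alone passed by either adjustment, and in the sarcomere list (25 measured) and the skeletal muscle list (10 measured) 0 genes did. Lists higher at the preset correlation alone were those of oxidative phosphorylation, PPAR alpha targets, insulin signalling and calcium handling (adjusted p = 0.43 each with an estimated correlation) and the antioxidant response (0.23). Of the oxidative phosphorylation genes (47 measured), Ndufs1 (0.12) passed over all genes and 5 were higher adjusted over the list alone. In the list of PPAR alpha targets and fasting genes (27 measured), 0 passed over all genes and 1 adjusted over the list alone, Pdk4 (0.40), which codes for a brake on glucose oxidation. The antioxidant list (23 measured) held 0 and 5, Gclm (0.27), Gstm2 (0.21), Nqo1 (0.22), Mt2 (0.30) and Sod2 (0.08). The insulin signalling list (32 measured) held 0 and 3, Fbxo32 (0.22), Deptor (0.15) and Phlpp1 (0.11), and the list of calcium handling and ion channels (25 measured) 0 and 3, Kcnd2 (0.22), Cacna1c (0.18) and Kcnj3 (0.08). The fry test passed for 2 lists, heat shock genes and skeletal muscle markers (adjusted p = 0.028). Over 24 h, 0 of the 35 list means passed the permutation test (smallest adjusted p = 0.11), against 2 without ZT19 replicate 1.

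Between ZT03 and ZT15, Scin was higher at ZT03 by 0.81 ± 0.12 (adjusted p with limma 0.0060), Mr1 by 0.69 ± 0.13, Fcgrt by 0.65 ± 0.13, the proteasome assembly gene Psmd5 by 0.63 ± 0.13 and Tmem59 by 0.63 ± 0.13. Lower at ZT03 were Rnu12, the small nuclear RNA of the minor spliceosome (-0.83 ± 0.20), Ier3 (-0.71 ± 0.12), Bst2 (-0.66 ± 0.13), Hspa8 (-0.64 ± 0.10, adjusted p = 0.0078) and the calcium-binding protein gene S100a11 (-0.61 ± 0.14). For each of these genes, which were chosen on the same hearts, all 4 ZT03 hearts lay beyond all 4 ZT15 hearts. Of the oxidative phosphorylation genes, Ndufs1 (0.19), Uqcrc2 (0.24) and Ndufb5 (0.28) were higher at ZT03 over all genes. Adjusted over the list alone 7 were higher and 10 lower, among the latter Sdhc (-0.34), Ndufa8 (-0.32) and Cox7a1 (-0.21). Of the lipid storage list, Lpl (-0.41) and G0s2 (-0.47) were lower and Agpat3 (0.21) higher. Insig1, which codes for a brake on sterol synthesis, was higher by 0.49, the autophagy gene Atg12 by 0.46 and Agtr1a by 0.45. Xirp1, a gene of the intercalated disc, was lower (-0.53), as was the creatine kinase gene Ckm (-0.36). Of the matrix genes, Dcn was higher (0.30) and Bgn lower (-0.26). Features averaged within these genes differed in size: -0.29 and -0.65 for G0s2, -0.12 and -0.52 for Ndufa8, -0.13 and -0.39 for Bgn, -0.26 and -0.46 for Ckm, and from -0.19 to -0.88 for Hspa8. Fibroblast markers had the largest median difference among the 14 cell type lists, 0.10.

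In all, 239 genes passed this comparison with limma, 195 higher and 44 lower at ZT03, of which 16 reached 1.5-fold (75 if the values were natural logs), and 2885 had an unadjusted p under 0.05. Of the 239 genes, 152 were among those of the time-of-day test. The count was 106 without ZT03 replicate 1, 69 without ZT03 replicate 2 and 25 without ZT03 replicate 3. It was 84 without ZT15 replicate 2, 52 without ZT15 replicate 3 and 55 without ZT15 replicate 4. Of the genes named by size, Scin, Hspa8 and Ier3 passed with each of the 24 hearts left out in turn, Mr1 with 22 of them, Fcgrt, Bst2 and Psmd5 with 20, Tmem59 with 18, S100a11 with 17 and Rnu12 with 10 (highest adjusted p 0.16). The split between higher and lower genes also moved, to 16 and 9 without ZT03 replicate 3, 35 and 17 without ZT15 replicate 3, 39 and 16 without ZT15 replicate 4, and 9 and 7 at an adjusted p under 0.01. With the mean of a cell type list as a covariate, 6 genes passed for fibroblast markers and, with limma, 0 for skeletal muscle markers, with 2121 and 1384 at an unadjusted p under 0.05. The median difference of the 239 genes was then 0.31 and 0.28. For lung markers as a covariate 18 genes passed, with a median difference of 0.35.

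Between ZT07 and ZT19, the smallest p-values belonged to Tppp (-0.34 ± 0.06), the chemokine scavenger receptor gene Ackr3 (-0.33 ± 0.06), Aen (-0.27 ± 0.05), Dpep1 (-0.31 ± 0.06) and Ciapin1 (-0.25 ± 0.05). Each had an adjusted p of 0.12 with limma and did not pass. All 4 ZT07 hearts lay below all 4 ZT19 hearts, which the choice by smallest p on the same hearts favours. Between ZT11 and ZT23 they belonged to Mtdh (0.53 ± 0.09), the Krüppel-like factor gene Klf15 (0.39 ± 0.07), Krtap10-10 (0.19 ± 0.03), the transferrin receptor gene Tfrc (-0.79 ± 0.14) and the splicing gene Luc7l3 (-0.34 ± 0.06). Each of these had an adjusted p of 0.10 with limma and did not pass. All 4 ZT11 hearts lay to one side of all 4 ZT23 hearts, again in genes chosen on these hearts. The separation is thus no support for a difference in either pair. With limma, 0 genes passed in either comparison, while 1238 and 1628 genes had an unadjusted p under 0.05. At ZT07 against ZT19, 3 genes passed without ZT15 replicate 1, 1 without ZT19 replicate 1 and 1 without ZT23 replicate 3. At ZT11 against ZT23, 4 passed without ZT11 replicate 1, 4 without ZT11 replicate 4, 1 without ZT03 replicate 4 and 1 without ZT11 replicate 2. Whether these pairs differ from ZT03 against ZT15 was not tested. Over all 22180 genes, the SD of the differences was 0.11 at ZT03 against ZT15, 0.077 at ZT07 against ZT19 and 0.084 at ZT11 against ZT23.

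In the 24 h test, the clock output list (35 measured) held 0 genes passing over all genes and 2 adjusted over the list alone, the stress gene Herpud1 (0.23, peak ZT17.1) and the sarcomere gene Tcap (0.26, peak ZT12.3). Klf15 passed the time-of-day test over all genes (adjusted p with limma 0.026). In the glucocorticoid list (20 measured), 0 passed over all genes and 4 adjusted over the list alone: Errfi1 (0.23, peak ZT6.20), Per1, the metallothionein gene Mt2 (0.28, peak ZT7.21) and Klf15 (0.13, peak ZT12.3). In the lipid storage list (25 measured) these counts were 0 and 4, with G0s2, Lpl, Agpat3 and Abhd5. In the extracellular matrix list (30 measured) they were 0 and 5, with Bgn, Serpinh1, Timp3, Thbs1 and Tgfb1. They were 0 and 2 for the sarcomere (Xirp1 and Tcap) and oxidative phosphorylation (Cox6a2 and Atp5h). They were 0 and 1 for fetal and hypertrophy genes (18 measured, Agtr1a), cholesterol synthesis (19 measured, Insig1), immediate early genes (25 measured, Ier3), endoplasmic reticulum stress (Herpud1) and PPAR alpha targets (Pdk4). The lists of glycolysis (31 measured), autophagy (30 measured), the cell cycle (26 measured) and the cytosolic ribosome (32 measured) held 0 by either adjustment, with 8, 4, 2 and 6 genes at an unadjusted p under 0.05. Insulin signalling, calcium handling and the antioxidant list also held 0, with 5, 5 and 8 such genes. Each of the 14 cell type lists held 0 in the 24 h test with limma by either adjustment, with 0 to 3 genes at an unadjusted p under 0.05. These lists covered atrial and ventricular cardiomyocytes, endothelium, fibroblasts, smooth muscle, macrophages, neutrophils, lymphocytes, fat, epicardium, Schwann cells, skeletal muscle, lung and blood, the last with 2 measured members.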

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

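Chosen only after the result was seen were the tests of ZT19 replicate 2, the test of a single heart behind the heat shock genes, and, for ZT03 against ZT15, the tests by the number of calls and by cell type covariates.

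In ZT19 replicate 2, Clock and Arntl were low and Per3, Nr1d2 and Dbp were high, while Nr1d1 was low (-0.62), opposite to its paralog Nr1d2, and 12 of the 21 core clock genes lay outside the range of the other 23 hearts, where the highest count of another heart was 4. A swap with another heart of the series would place it near the hearts of another time point, but over clock output genes its smallest distance from the mean of a time point, its own, was 0.452, where the largest such distance of another heart was 0.207. Poor quality of the array would move other genes alike, but the share of all genes outside the range was 0.145 of the share of core clock genes. A heart whose clock ran, from an animal of another genotype under this label, was tested by clock output genes. Of these, 18 of 35 lay outside the range too, where the highest of 10000 random lists had 11. Fmo2 (1.04), Wee1 (0.87) and Nampt (0.83), named after their values were seen, were among the 18. The count takes no account of direction or time of day. It cannot tell another genotype from another cause that moves clock genes and their outputs together. No wild-type heart was analysed here and the deposited values hold no separate reading of the deleted exon. A running clock in this heart thus stays a hypothesis found and tested on the same hearts.

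Of the opposite time points, ZT03 against ZT15 held all 239 calls. With the level of small nuclear and nucleolar RNA as a covariate, there were 252 calls, with 0.988 of the median difference of the 239 genes left. This argues against the level of small RNA as the whole cause. Genes with a feature above 8 before centring had a median ZT03 minus ZT15 of 0.046, against -0.0051 over all genes. Whether a shift that depends on level adds to the calls was not tested. With 1 of the 8 hearts left out, 25 to 281 genes passed, the 25 without ZT03 replicate 3 and 24 of them among the 239. The other pairs had at most 4 with a heart left out, which argues against a single heart as the whole cause, though the effect of 1 heart was not told apart from that of fewer hearts. The share of the median left without 1 heart, 0.965 at the lowest, decides nothing, since the genes were chosen on these hearts. Another cell type stays open: the largest median of a list, that of fibroblasts, was 0.292 of the median of the called genes, but the upper quartile of its members was 0.24. With fibroblast or skeletal muscle markers as a covariate, 6 and 0 genes passed with limma (2121 and 1384 at an unadjusted p under 0.05). The median difference then went from 0.34 to 0.31 and 0.28 (0.806 of it left, the lowest of 14 lists). The median SE rose from 0.072 to 0.083 and 0.089. With lung markers 18 genes passed, though 1.02 of the median difference was left and the median SE was 0.088. Calls were thus also lost with a list that left the difference in place. Whether a covariate removed a cell type or a part of the difference itself was not tested. Called genes are in the fibroblast list (Dcn) and the skeletal muscle list (Ckm, also expressed in heart muscle). RNA integrity was not tested, the labels name no batch, and a biological difference between these times of day stays open.

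Of 20 heat shock genes, 4 were lower in the light phase over all genes, while the shift of the list did not hold with an estimated correlation (adjusted p = 0.15). The mean of the immediate early genes as a covariate left 0.963 of the median difference of these 4 genes, and the small RNA covariate left 1.00 of it, with 4 of 4 genes still passing in each case. The lowest share of the list's median left without 1 heart was 0.766. These values argue against a single heart and against the level of small RNA as the whole cause. They also argue against stress at collection as the whole cause, as far as immediate early genes mark it. The covariate shares cover only these 4 genes, which were chosen on these hearts. Skeletal muscle markers were lower in the light phase too (adjusted p = 0.028 with fry). Whether skeletal muscle content adds to the heat shock difference was not tested. Feeding, activity and body temperature follow the light cycle, were not measured and stay open as biological explanations.

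The real grouping was set against other groupings of the same hearts, 100 in all for the tests over 24 hearts and 35 for 8 hearts, the real one included. Chance alone is unlikely for time of day (329 genes, highest other 1) and the 24 h rhythm (14, highest other 2). The same holds for light against dark (84, highest other 2) and ZT03 against ZT15 (239, highest other 2). In each, 1 grouping, the real one, reached the count, which is the smallest share that 100 or 35 groupings can give. Other groupings leave real differences in the spread, which can lower their counts. Chance cannot be excluded for the 12 h component, where 7 of 100 groupings gave at least the 1 gene of the real one and the highest other gave 4. At ZT07 against ZT19 and at ZT11 against ZT23 the real count was 0, which any of the 35 groupings reaches, so the comparison says nothing about chance there; the highest other gave 1 in each.

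Single hearts lay far from the other 3 of their time point in 35 of 666 groups of 4, where chance gives 33.3, about 1 in 20. The values are differences from the mean of the other 3 hearts. In ZT19 replicate 2 they were -0.58 for Clock, 0.71 for Nr1d2, 0.64 for Dbp and -0.12 for Dpep1. In ZT23 replicate 1 they were -0.12 for Clock, -0.45 for Nr1d2 and -0.33 for Errfi1. In ZT11 replicate 4 they were 0.54 for Nabp1, -0.68 for Tfrc, 0.069 for the mean of the antioxidant list and 0.040 for that of lymphocyte markers. In ZT11 replicate 1 they were -0.12 for Rorb and -0.37 for Errfi1, in ZT11 replicate 2 -0.18 for Arntl2 and in ZT11 replicate 3 -0.27 for Mtdh. Dbp differed by 0.30 in ZT03 replicate 1 and by 0.29 in ZT15 replicate 1, where Tppp differed by -0.16 and blood markers by 0.094. Timeless differed by -0.19 in ZT19 replicate 3 and Prrx1 by 0.23 in ZT19 replicate 4. Bst2 (-0.45), S100a11 (-0.39) and the mean of the calcium handling list (0.108) stood apart in ZT03 replicate 4, Mospd1 (-0.20) in ZT03 replicate 2 and skeletal muscle markers (-0.067) in ZT03 replicate 3. Agtr1a (-0.20) and Tmem63b (-0.22) did in ZT07 replicate 1 and Tmem65 (-0.12) in ZT07 replicate 4. In ZT23 replicate 3 the differences were -0.14 for Cryab, -0.056 for ribosomal genes and 0.036 for neutrophil markers. In ZT23 replicate 4 they were -0.148 for PPAR alpha targets, -0.099 for the insulin signalling list and 0.069 for skeletal muscle markers.

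Among the 10830 features without a single gene symbol, which no comparison above used, 11 passed the time-of-day test with limma, and 964 had an unadjusted p under 0.05. The counts passing were 18 for ZT03 against ZT15 (1151 at an unadjusted p under 0.05), 4 for light against dark and 3 for the 12 h test.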

How the results depend on the processing

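Chosen only after the data were seen were robust moderation, each feature tested on its own, genes with a feature above 8, the small RNA covariate, leaving out both arrays of lowest weight, the core clock count adjusted over the list alone under each alternative, leave-outs for the gene lists, and covariates from cell type lists other than atrial and blood markers.

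No named gene that passed in the fit reported above or in the alternative was scored as reversed. For genes named by the time-of-day test, which has no direction, only the threshold was scored. Robust moderation, no moderation and a stricter threshold leave the estimates unchanged, so a reversal could not occur there. Named genes that passed kept their side of the threshold, and their direction where scored, in 513 of 637 values under other settings. They fell short in 124. With hearts left out they did so in 1030 of 1296 and fell short in 266. Genes that had not passed came to pass in 10 values and 7 values. The direction or peak time of genes that passed in neither fit moved in 1 value and 5 values. Where a count moved, the cause was not tested, except that a stricter threshold or a minimum fold lowers the count by construction. The median difference and its SE were followed for fibroblast, skeletal muscle and lung markers as a covariate.

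With quantile normalization, 30 genes passed the 24 h test, 7 the 12 h test, 144 light against dark, 8 ZT07 against ZT19 and 1 ZT11 against ZT23. Centring each array gave 6 genes in the 12 h test. Robust moderation and each feature on its own gave 0 there. Without moderation, counts were 86 for time of day, 4 for 24 h, 0 for 12 h, 45 for light against dark and 104 for ZT03 against ZT15. Highest at ZT03 were then 47 genes and lowest at ZT11 25. Array weights gave 59 for 24 h, 14 for 12 h, 430 for ZT03 against ZT15 and 1 for ZT07 against ZT19. The atrial covariate gave 3 for 24 h, 19 for 12 h and 131 for ZT03 against ZT15, and the blood covariate 12 for 12 h and 143 for ZT03 against ZT15. At an adjusted p under 0.01, counts were 6 for time of day, 3 for 24 h, 0 for 12 h, 8 for light against dark, 16 for ZT03 against ZT15 and 1 for core clock genes adjusted over the list alone. With 12 h terms beside, 74 genes and 1 core clock gene passed the 24 h test. At 1.5-fold, 2 genes were left for 24 h and, with limma, 0 for light against dark, where 2336 had an unadjusted p under 0.05. A fit of 2 groups gave 34 for light against dark, and a fit of 8 hearts 107 for ZT03 against ZT15. The 461 genes with a feature above 8, tested alone, gave 135 for time of day (41 of them shared with the 329), 20 for 24 h, 56 for 12 h, 54 for light against dark, 107 for ZT03 against ZT15 and 4 for ZT07 against ZT19. Over these 461 genes chance was not tested with other groupings. The small RNA covariate gave 12 for 12 h. For ZT03 against ZT15, markers of fibroblasts as a covariate gave 6, smooth muscle 447, macrophages 68, neutrophils 89, fat 73, lung 18 and skeletal muscle, with limma, 0 (1384 at an unadjusted p under 0.05), the other 5 lists 224 to 334. Without both arrays of lowest weight, counts were 0 for 12 h, 365 for ZT03 against ZT15, 1 for ZT07 against ZT19, 3 for ZT11 against ZT23 and 1 for core clock genes adjusted over the list alone. Of the 10 gene lists in light against dark, 0 passed with an estimated correlation and 2 with fry.

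With each heart left out in turn, counts ranged from 28 to 467 for time of day, 3 to 45 for 24 h, 0 to 148 for 12 h, 51 to 183 for light against dark, 25 to 326 for ZT03 against ZT15, 0 to 3 for ZT07 against ZT19 and 0 to 4 for ZT11 against ZT23. Core clock genes passing over all genes ranged from 0 to 0 and adjusted over the list alone from 3 to 7. Gene lists passing in light against dark ranged from 9 to 13 and over 24 h from 0 to 2, the 2 without ZT19 replicate 1. The heat shock median ranged from -0.134 to -0.087.

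With the replicate number as a block, 218 genes passed time of day and 0 the 12 h test, and the other counts were 11 for 24 h, 76 for light against dark and 197 for ZT03 against ZT15. Deviations of hearts with the same number correlated at 0.0024 on average, against -0.00078 for other numbers, which gives no sign of a general pairing. Of 60 pairs with the same number, 8 were over 0.1, and 10 of 24 arrays correlated best with one of their own number. How many such best matches chance gives was not computed, so a pairing of some hearts cannot be excluded.

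The planned stricter filter on level and the intensity trend were not run, since the number grid gives 2 classes of level and no order within them. The planned fits with no filter and with the mean of a gene's features equal the values reported. Signal over background is unknown, so what it limits cannot be said.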

Other observations

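Chosen only after the data were seen were all tests of this part.

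Across hearts of all time points, the mean of the activator genes Arntl, Npas2 and Clock ran opposite to the mean of 11 target genes. The targets were Per1, Per3, Cry2, Nr1d1, Nr1d2, Ciart, Dbp, Tef, Hlf, Bhlhe40 and Bhlhe41, without Cry1. Over the 24 hearts Pearson's r was -0.78 (permutation p = 4e-05, adjusted 0.00012) and Spearman's rho -0.70 (permutation p = 0.00023, adjusted 0.00069), and r was -0.61 without the 2 hearts farthest from the median. Without ZT19 replicate 2, over 23 hearts, r was -0.63 (permutation p = 0.0014, adjusted 0.0021) and rho -0.66 (permutation p = 0.0010, adjusted 0.0015), and r was -0.55 without the 2 farthest. Within time points, r was -0.62 (permutation p = 0.18, adjusted 0.18) and rho -0.27 (permutation p = 0.26, adjusted 0.26), and r was -0.055 without the 2 farthest, so that value rests on those hearts. These 3 relations were computed with 100000 permutations. Over 24 and 23 hearts, values were shuffled across time points, so these p-values include differences that both sets share by time of day. They do not measure a relation between hearts of the same time point. The activators averaged 0.16 ± 0.06 (SD, n = 4) at ZT03 and -0.18 ± 0.05 (SD) at ZT11, the targets -0.06 ± 0.01 (SD) and 0.08 ± 0.07 (SD).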
